A study of Mus musculus with 2 samples.

How the data were processed

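Both libraries were B2 SINE-seq libraries of NIH 3T3 mouse fibroblasts infected with MHV68, forming 1 group with replicates 1 and 2. Per the labels' protocols, cells were infected at a multiplicity of 5 for 1 h and kept for a further 24 h, and 200 µg of total RNA was extended with a B2-specific oligonucleotide. Extension products were resolved on 8% polyacrylamide gels with 7 M urea, and the 130 to 180 bp region was recovered. Products were tailed with deoxyguanosine and amplified in 10 PCR cycles with a primer against the tail and the B2 oligonucleotide, per the labels' protocols. The sequence of the B2 oligonucleotide is not given in the sources used here. This selection limits what could be seen: a copy needed a matching primer site and a product within the gel region. The PCR step gives repeat reads of the same molecule, so read counts overstate precision.

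CASAVA 1.9 and BWA were named per the submitters' processing notes, with mm10 as the genome build and no version for BWA. The design text adds that reads over the B2 elements of the RepeatMasker annotation were counted and that RPKM was computed with a utility for alignment files. Each deposited table listed 372923 B2 copies with position, strand, length, read count, CPM and RPKM. Read counts were whole numbers per copy, counted without regard to strand and with a partial setting for reads with multiple positions, per the file headers. B2 copies are nearly alike, so reads of 1 copy can be counted on another, and how the partial setting acted on reads is not given in the sources used here. CPM was scaled to the total of the reads counted over all B2 copies, per the file headers, and the sums of the counts matched the totals in the headers with a difference of 0 reads in each library. RPKM was CPM divided by the length of the copy in kb, per the file headers, and all values of both columns were recomputed from the counts. RPKM assumes reads along the whole copy, while extension from a fixed primer gives 1 product per molecule, so RPKM raises short fragments relative to CPM. The input alignments were named differently in the headers: the name for replicate 2 mentions trimming and BWA, and that for replicate 1 does not. Whether the libraries were trimmed and aligned alike is not given in the sources used here.

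Replicate 1 held 6065686 counted reads and replicate 2 held 8007827, a ratio of 1.32. One read equalled 0.165 CPM in replicate 1 and 0.125 CPM in replicate 2. For a count of 0, the upper limit was set at 3 reads. Copies detected in a library had a median of 13 reads in replicate 1 and 14 in replicate 2. Annotated copies were 11 to 301 bp long with a median of 178 bp. The libraries were counted as 2 samples because the design text calls them biological replicates. The files were also checked for a single library given under both names: the chi-square of their counts over copies was 79.7 times its degrees of freedom.

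A copy was called detected with at least 1 read. Shares carry exact (Clopper-Pearson) 95% binomial intervals per library and mean ± SD over both libraries. Signal was the sum of reads. Length classes finer than the limit of 150 bp were chosen after the data were seen, and the class of 185 to 194 bp joins the adjacent 5-bp classes with the highest share detected. Replicate agreement was described by the overlap of detected copies, correlations of log2(RPKM + 1), and an exact two-sided binomial test of the reads of the 2 libraries. That test was run on copies with at least 10 reads in total, given the library totals, with Benjamini-Hochberg adjustment at 0.05. On simulated libraries with the real means and totals, it recovered 33 of 100 copies changed 2-fold and 84 of 100 changed 4-fold, and called 6 of 48849 unchanged copies. The simulation drew Poisson counts, without repeat reads from PCR or any other spread between libraries. Its few false calls therefore say nothing about the rate in the real counts. No model of groups was fitted, because the series holds 1 group.

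Gene positions came from GENCODE M21, which is on the same assembly as mm10. Copies were assigned with bedtools 2.31.1 to exons where they overlapped any exon, otherwise to introns or to intergenic space. The placement was checked on 6629 copies of at least 150 bp that lie wholly inside exons, whose sequence was taken from the transcripts: a B box stood on the strand of the copy in 32.3% and on the other strand in 0.121%. A subfamily name per copy was not used here, so the planned share of signal by B2 subfamily was not made and gene lists were matched on length class alone.

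Gene lists of about 30 genes each were fixed before the data were examined: interferon-stimulated genes, the NF-kB pathway and targets, the RNA polymerase III machinery, housekeeping genes, and markers of fibroblasts, neurons, hepatocytes, muscle and leukocytes. For each list, the share of its B2 copies with reads was given as a percentile among 10000 random sets of B2 copies inside genes, with the same numbers below and from 150 bp. In 200 simulated lists with no difference, 20 fell below percentile 5 or above percentile 95. Copies of 1 gene are not independent, so percentiles describe these libraries and are not p-values.

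Named copies followed a rule also fixed before the data were examined. The rule took the 10 copies with the highest mean RPKM among 36838 copies with at least 3 reads in each library, the host or nearest gene of ranks 11 to 25, and, per list, the 2 copies inside list genes with the highest mean RPKM among those detected in both libraries. One copy that the rule names is not reported here. Alternatives fixed at the same time were detection at 3 reads, a pseudocount of 0.1, summed RPKM as signal, copies of at least 150 bp, assembled chromosomes, protein-coding genes, genes extended 5 kb downstream, removal of the highest copy, and each library alone. Added after the data were seen were detection at 10 reads and 3 other ways of matching the gene lists. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.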

Results

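The data describe on which genomic copies of the B2 short interspersed element (SINE) reads were counted in mouse fibroblasts infected with a herpesvirus. B2 copies are nearly alike, so a read counted on 1 copy can come from another, also for the single copies named below. B2 elements are short retrotransposons derived from a transfer RNA. RNA polymerase III transcribes them from a promoter inside the element, made of an A box and a B box. NIH 3T3 is an established mouse embryonic fibroblast line, and murine gammaherpesvirus 68 (MHV68) is a gammaherpesvirus that infects rodents. Cells were infected at a multiplicity of 5 for 1 h, washed and kept for 24 h. In B2 SINE-seq, total RNA was extended from a B2-specific oligonucleotide, products of 130 to 180 bp were cut from a gel, and these were tailed, amplified and sequenced. The series formed 1 group of 2 libraries, described by the design text as biological replicates. No uninfected library was analysed here, so the values describe infected cells and no effect of infection was measured. Replicate 1 held 6065686 reads and replicate 2 held 8007827 reads over 372923 annotated B2 copies. With 1 group of 2 libraries, the smallest p that an exact two-sided test over paired values can give is 0.5, so no test between conditions was made. Reads carried no molecular identifiers in the values used here, so all intervals and floors cover counting error only.

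The first question was how many B2 copies gave reads in infected fibroblasts. Most annotated B2 copies gave none: 297851 of 372923 copies (79.9%) had no read in either library. A total of 51451 copies had at least 1 read in replicate 1, which was 13.8% of the annotated copies (exact 95% binomial interval 13.7 to 13.9%). Replicate 2 had 70208 copies with reads, or 18.8% (18.7 to 19.0%). Thinned at random to the read total of replicate 1, replicate 2 still had 68335 copies with reads, 1.33 times those of replicate 1. The read total therefore accounts for little of this difference. The mean share was 16.3% ± 3.56 (SD, n = 2). Both libraries had reads on 46587 copies. A count of 0 allowed up to 3 reads, equal to 0.495 CPM in replicate 1 and 0.375 CPM in replicate 2, so copies without reads were undetected at this depth and not shown to be silent.

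The sets of B2 copies with reads overlapped strongly between the libraries, while the level of single copies did not repeat closely. Of the copies detected in replicate 1, 90.5% were also detected in replicate 2, and 66.4% of those of replicate 2 were detected in replicate 1. The 46587 shared copies were 4.81 times the 9686 that independent lists of these sizes would share. They held 99.3% of the reads of replicate 1 and 96.2% of those of replicate 2. Across the 75072 copies detected in either library, log2(RPKM + 1) correlated with Pearson's r = 0.611 and Spearman's rho = 0.516. Among the 5329 copies with at least 100 reads in each library, r was 0.691 and rho 0.617. These correlations are across copies, which are not independent replicates.

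Among the 5329 B2 copies with at least 100 reads in each library, the median copy differed 1.60-fold between the libraries. This choice leaves out copies that were high in 1 library alone. Of the 5329, 65.9% lay within 2-fold and 9.57% differed by over 4-fold. An exact two-sided binomial test of the reads of the 2 libraries, with Benjamini-Hochberg adjustment at 0.05, found a difference for 35498 of 50083 copies (70.9%), 14397 higher in replicate 1 and 21101 higher in replicate 2. This test compares the libraries with sampling noise and says nothing about conditions. The libraries also differed in how their alignments were named in the file headers, so culture, library and alignment differences cannot be separated here.

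**Figure D1:**
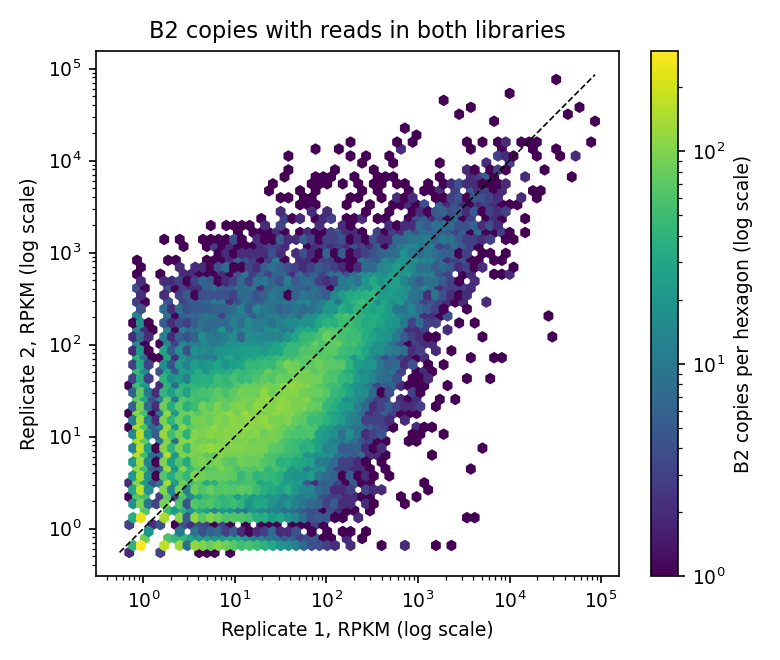
Each hexagon collects B2 copies by RPKM in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), for the 46587 copies with reads in both libraries, and its colour gives the number of copies on a log scale. The dashed line marks equal values, and copies spread on both sides of it, with r = 0.634 across these copies.

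A small part of the B2 copies carried most of the B2 reads. The 10 copies with most reads in each library held 9.42% of the reads of replicate 1 and 7.43% of those of replicate 2 (8.42% ± 1.40, SD, n = 2). The leading 100 copies held 25.2% and 23.6%, and the leading 1000 held 56.3% and 53.3%. To reach 50% of the reads took 655 copies in replicate 1 and 802 in replicate 2. The single highest copy held 1.51% of the reads of replicate 1 (exact 95% binomial interval 1.503 to 1.522%), and a different copy held 1.45% of those of replicate 2 (1.44 to 1.45%). The lists of leading copies overlapped in part: 4 of 10, 43 of 100 and 568 of 1000 were in both lists.

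The 9 B2 copies with the highest mean RPKM lay on 5 chromosomes, 4 of them inside genes and 5 between genes. All 4 genic copies were intronic, and 3 lay only antisense to their host genes. Antisense and sense refer to the annotated strand of the B2 copy, because reads were counted without regard to strand. Positions are in mm10, counted from 1. The highest copy lay at chromosome 14, 47131136 to 47131311, between genes and 10697 bp from the predicted gene Gm49132. It had 57371 ± 40395 RPKM (SD, n = 2), from 91740 reads in replicate 1 and 40600 in replicate 2. The next lay at chromosome 11, 94969958 to 94970147, in an intron of Sgca, which encodes alpha-sarcoglycan of the dystrophin-associated complex. It had 52866 ± 32871 RPKM, from 34140 and 115800 reads. A copy at chromosome 17, 70797265 to 70797455, lay in introns of Dlgap1, a postsynaptic scaffold gene, and of the overlapping transcript gene AC079441.1, and had 51284 ± 14750 RPKM. A copy at chromosome 6, 47780506 to 47780689, lay 935 bp from Rny3, a Y RNA gene that RNA polymerase III also transcribes, and had 48587 ± 43917 RPKM. The copy in an intron of E4f1, a zinc finger transcription factor gene, lay at chromosome 17, 24469559 to 24469725, and had 36209 ± 10075 RPKM.

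The remaining 4 of these copies had 25656 to 30920 mean RPKM. The copy in an intron of Cyp46a1, which encodes cholesterol 24-hydroxylase, lay at chromosome 12, 108359161 to 108359341, and had 56472 reads in replicate 1 and 15078 in replicate 2. A copy at chromosome 6, 86513611 to 86513798, lay 93 bp from the long noncoding RNA gene Gm44386 and had 55750 and 16114 reads. Another on chromosome 6, 70817256 to 70817432, lay 25024 bp from Rpia, the ribose 5-phosphate isomerase gene, and had 10313 and 70406 reads. A copy at chromosome 11, 85270573 to 85270750, lay 26702 bp from Gm22587 and had 48221 and 9479 reads. Across the 9 copies the libraries differed by 1.49 to 6.72-fold, and each differed by the exact binomial test.

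**Figure D2:**
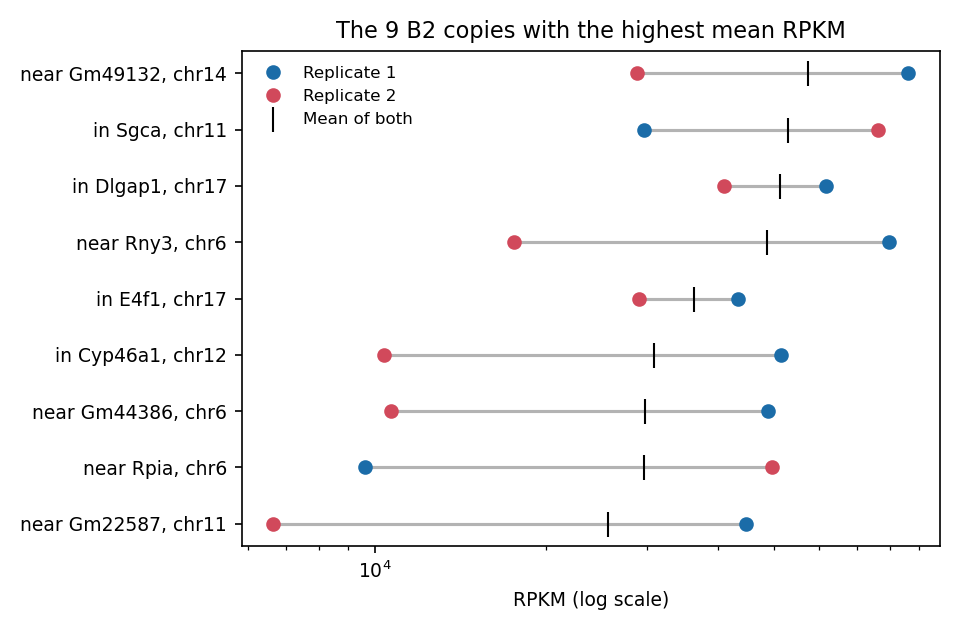
RPKM (x axis, log scale) of the 9 B2 copies with the highest mean RPKM, named by host or nearest gene and chromosome (y axis), with replicate 1 in blue, replicate 2 in red and the mean as a black bar. The libraries lie closest for the copy in E4f1 (1.49-fold) and farthest apart for the copy near Gm22587 (6.72-fold).

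Of the B2 copies ranked 11 to 25, 6 lay inside genes and 9 between genes. Those inside genes lay in Aldh5a1, Atl3, Fam20b, Arl5c, March10 and Palm. Aldh5a1 encodes succinate semialdehyde dehydrogenase and Atl3 an endoplasmic reticulum GTPase. The copy in Arl5c was the only 1 of the leading 25 to overlap an exon. Nearest genes of the others were Tnfsfm13, Opn1sw, Fgfbp3, Lrr1, Prkci, 4931406P16Rik, Gm23975, Gm22587 and Plekhm2. Chromosome 11 held 7 of the leading 25 copies. Of the 11 copies inside genes, 9 lay only antisense to the host gene; among all B2 copies inside genes on a single strand, 57.2% were antisense. Differences between the libraries at ranks 11 to 25 ran from 1.06-fold, near 4931406P16Rik, to 260-fold, for a 68-bp fragment near Gm22587. That fragment lies beside the 178-bp copy of rank 9.

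Reads came almost wholly from B2 copies of near full length. Copies of at least 150 bp numbered 270522, or 72.5% of the annotation, and held 97.6% of the reads of replicate 1 and 98.7% of those of replicate 2 (98.2% ± 0.742, SD, n = 2). Of these copies, 18.1% and 24.3% had reads, against 2.52% and 4.31% of the 102401 shorter copies. Copies of 185 to 194 bp stood highest, with 32.8% and 42.1% detected and 48.1% and 57.1% of all reads on 19.0% of the copies. Of the copies of 200 bp or more, 2.33% and 3.38% had reads. The order of these length classes was the same in both libraries.

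**Figure D3:**
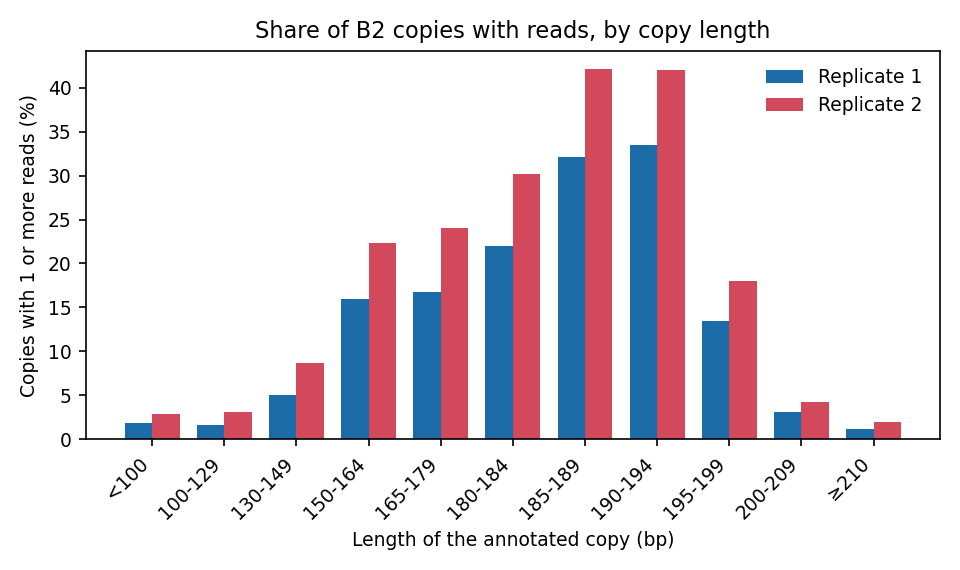
Share of B2 copies with at least 1 read (y axis, percent) by the length of the annotated copy in bp (x axis), with replicate 1 in blue and replicate 2 in red. Shares are highest at 185 to 194 bp (32.8% and 42.1%) and low below 150 bp (2.52% and 4.31%) and from 200 bp up (2.33% and 3.38%).

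B2 reads followed the distribution of B2 copies over exons, introns and the space between genes. Introns held 51.3% of the copies and 47.9% and 50.3% of the reads (49.1% ± 1.69, SD, n = 2). Intergenic copies were 45.5% of the annotation and held 48.3% and 46.4% of the reads (47.4% ± 1.35). Copies that overlap exons were 3.18% of the annotation and held 3.75% and 3.27% of the reads (3.51% ± 0.339). Orientation relative to the host gene gave opposite results in the libraries. Sense copies were detected more often than antisense copies in replicate 1 (16.0% against 14.1%) and less often in replicate 2 (18.0% against 20.9%), so no direction is given. The intergenic share of reads was 33.5% when genes were extended 5 kb downstream, a setting that also lowers the intergenic share of copies.

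Mean CPM per B2 copy was highest on chromosomes 11, 19 and 17 and lowest on the sex chromosomes in both libraries. Other chromosomes also departed from their share of copies. For example, chromosome 6 held 7.79% and 5.79% of the reads on 5.44% of the copies, and chromosome 1 held 4.72% and 4.65% on 6.46%. Much of the reads on chromosome 6 lay on leading copies near Rny3 (1.47% and 0.323% of all reads), Gm44386 (0.919% and 0.201%), Opn1sw (0.672% and 0.211%) and Rpia (0.170% and 0.879%). Copies on chromosome 6 were detected less often (11.4% and 15.5%) than all annotated copies (13.8% and 18.8%). Chromosome 11 held 7.15% of the B2 copies and 13.7% and 14.5% of the reads (14.1% ± 0.553, SD, n = 2). Part of this excess lay in leading copies, such as those in Sgca (0.563% and 1.45% of all reads) and near Gm22587 (178 bp, 0.795% and 0.118%). Copies on chromosome 11 were also detected more often (17.3% and 22.4%) than all annotated copies. They had a mean of 5.14 and 5.44 CPM, against 2.68 CPM over all annotated copies in each library. Copies on chromosome 19 were nearly level with these, at 4.33 and 5.32 CPM, and held 4.11% and 5.05% of the reads on 2.54% of the copies. Copies on chromosome 17 had 3.96 CPM in both libraries and held 5.76% of the reads of each on 3.90% of the copies. Much of this excess lay in the leading copies in Dlgap1 (1.18% and 0.780% of all reads) and E4f1 (0.724% and 0.486%). The X chromosome held 4.58% of the copies and 1.51% and 1.30% of the reads (1.40% ± 0.148). Its copies were also the least often detected among chromosomes other than Y, at 10.998% and 15.4%, while the highest shares were 17.6% on chromosome 19 in replicate 1 and 22.7% on chromosome 15 in replicate 2. On the Y chromosome, 5 and 13 of 5878 copies had reads, with 27 and 54 reads in all. The 701 copies on 32 unplaced or unlocalised contigs had no reads in either library.

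B2 copies inside 9 gene lists were compared with random sets of B2 copies inside genes, matched on length class. Copies inside neuronal genes were detected least often of the 9 lists in both libraries. Copies inside interferon-stimulated genes were detected most often in replicate 1. In replicate 2 the list with the highest share depended on the read minimum: housekeeping genes led at 1 read (25.6%) but had 20.5% at 3 reads, when interferon-stimulated and leukocyte genes each had 22.1%. The 30 neuronal genes held 1408 copies, of which 4.97% had reads in replicate 1 (exact 95% binomial interval 3.90 to 6.24%) and 6.96% in replicate 2 (5.69 to 8.42%). Matched sets had medians of 15.0% and 19.7%, and the list lay below each of 10000 such sets in both libraries. Long synaptic genes held many of these copies, such as Cntnap2, a cell adhesion gene of the neurexin family, with 6 and 8 of 182 copies detected. The highest copies of the list lay in introns of Syn1, the synapsin I gene (552 ± 772 RPKM, SD, n = 2), and of Cntnap2 (334 ± 106 RPKM). The Syn1 copy had 7 reads in replicate 1 and 1671 in replicate 2.

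Interferon-stimulated genes held 131 copies. Of these, 27.5% had reads in replicate 1 (20.0 to 36.0%) and 25.2% in replicate 2 (18.0 to 33.5%), against medians of 15.3% and 19.8% in matched sets. The list lay at percentile 99.995 in replicate 1 and 92.3 in replicate 2. Copies with reads in both libraries lay in 12 of the 24 list genes that hold a B2 copy. The highest lay in introns of Stat2, a signal transducer of type I interferon (226 ± 102 RPKM), and of Adar, an RNA-editing adenosine deaminase (147 ± 68.7 RPKM). Chosen after the values were seen, Ddx58, which encodes the RNA sensor RIG-I, had 7 of 17 copies detected in each library, and Oasl1 had 5 of 6. Oas3 had 0 of 9 and Eif2ak2, the gene of the RNA-dependent kinase PKR, 0 of 6. When sets were matched on distance to the nearest gene start as well, the percentile stayed at 99.8 in replicate 1 and was 74.0 in replicate 2.

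Genes of the RNA polymerase III machinery held 226 copies, of which 19.5% (14.5 to 25.2%) and 25.2% (19.7 to 31.4%) had reads, against 14.6% and 19.5% in matched sets (percentiles 97.8 and 98.7). The highest copies lay in introns of Polr3gl, a polymerase subunit gene (2150 ± 607 RPKM), and of Brf1, a subunit gene of the initiation factor TFIIIB (627 ± 341 RPKM). Matching on distance to the nearest gene start gave percentiles of 85.5 and 89.995. Genes of the NF-kB pathway and its targets held 151 copies, with 18.5% and 23.8% detected (percentiles 88.5 and 89.3). The leading copies were in Rela, the p65 subunit gene (687 ± 306 RPKM), and in Traf2, a signalling adaptor gene, where the copy was a 28-bp fragment (377 ± 275 RPKM).

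Among the cell type lists, shares at 1 read for fibroblast and leukocyte genes lay close together, and those for muscle genes were lower. At 10 reads the fibroblast shares were 14.6% and 11.5% and the leukocyte shares 9.73% and 17.7%, so their order differed between the libraries. Genes of the fibroblast list, labelled as low in other tissues, held 130 copies, with 16.9% and 20.8% detected at 1 read (percentiles 75.5 and 65.1). That label was not checked here against expression in tissues. The leading copies of the fibroblast list lay in Loxl1, a lysyl oxidase gene (2330 ± 3182 RPKM, 93 and 7041 reads), and in Twist2 (365 ± 349 RPKM). The Twist2 copy was a 39-bp fragment with 28 and 191 reads. Leukocyte genes had 17.7% and 22.1% of 113 copies detected (percentiles 83.1 and 79.4), led by Fcgr1, an immunoglobulin receptor gene (447 ± 127 RPKM), and Cd4 (397 ± 1.58 RPKM). Copies inside hepatocyte genes were detected at 9.32% and 17.8% of 118 (percentiles 3.15 and 29.3), led by Hnf4a with its antisense gene Hnf4aos (392 ± 321 RPKM) and by G6pc (324 ± 454 RPKM, 3 and 960 reads). Muscle genes had 10.7% and 13.1% of 488 copies detected (percentiles 0.32 and 0.01), led by Myom2 (3888 ± 2238 RPKM) and Ttn, the titin gene (284 ± 270 RPKM). Dmd, the dystrophin gene, held 143 of these copies, and without it the shares were 12.2% and 14.8%. Ryr2, a calcium channel gene chosen after its values were seen, had 1 of 99 copies detected in each library, and without it the shares were 13.1% and 16.2%. Against random genes with like numbers of copies, the muscle list lay at percentiles 25.7 and 14.1. Housekeeping genes had 14.1% and 25.6% of 78 copies detected (percentiles 56.6 and 96.3), led by Eno1, the alpha-enolase gene (446 ± 531 RPKM), and Eef1a1 (56.18 ± 12.04 RPKM).

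The median RPKM of the copies was 0 in each of the 9 lists and both libraries, because most copies had no reads. Of the 18 copies named for the lists, 16 differed between the libraries by the exact binomial test, and 9 were higher in replicate 2. The copies in Cd4 (adjusted p = 0.982) and Eef1a1 (adjusted p = 0.136) did not differ by this exact test.

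**Figure D4:**
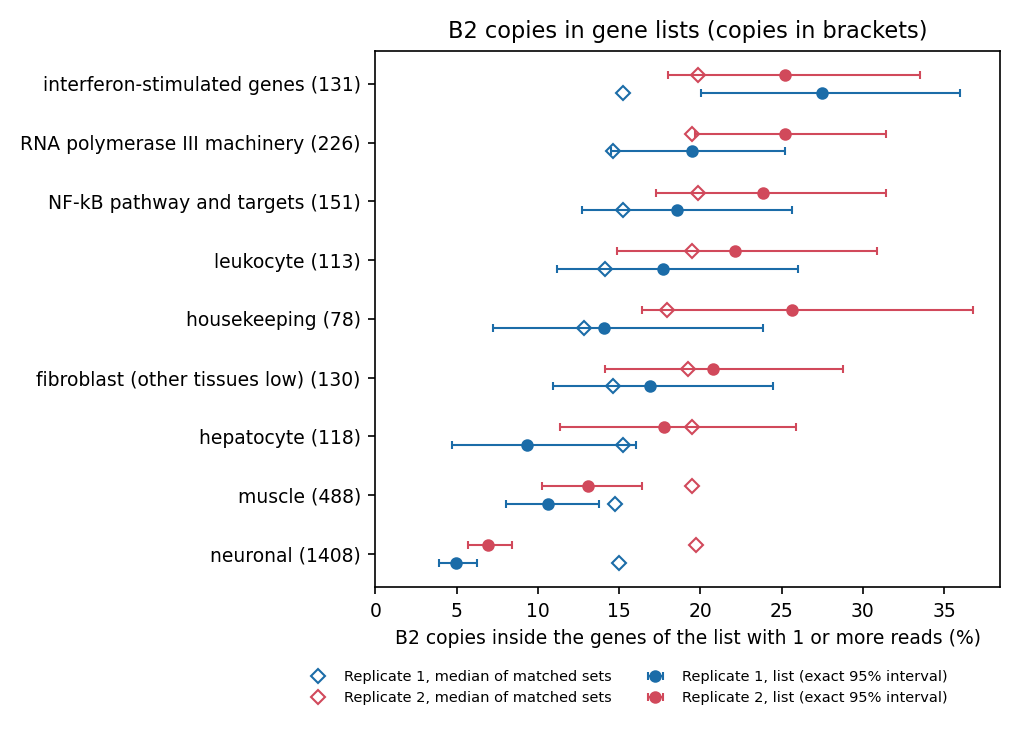
Share of B2 copies inside the genes of each list with at least 1 read (x axis, percent), with the number of copies in brackets beside the list names (y axis), replicate 1 in blue and replicate 2 in red, exact 95% binomial intervals as bars. Open diamonds mark the median of 10000 random sets matched on length class; neuronal genes lie at 4.97% and 6.96%, far left of their matched medians of 15.0% and 19.7%.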

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

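Matching of the gene lists on 4 length classes, on length and gene-start distance or by random genes, and detection at 10 reads, were chosen after the data were seen. Each value here is the mean of both libraries, and the cause of each shift was not tested unless stated. Of 234 values recomputed under settings that keep both libraries, 69 moved by more than 1 SD between the libraries, for counts by more than 1.5 times, or, for the overlap ratio and r, which have no SD, out of the 95% interval over copies. Some of the 234 could not change under their setting, so 69 of 234 understates how often values moved. Examples are list percentiles of mean log2(RPKM + 1) at other read minimums and the exon share with genes extended 5 kb downstream. With detection at 10 reads, 35324.5 copies per library (9.47%) and 23380 in both remained, with 12.6% of copies of at least 150 bp and 1.32% of shorter copies, so the longer copies remained ahead. Among copies of at least 150 bp, 21.2% were detected, the overlap was 3.75 times that of independent lists and r was 0.627. At 3 reads these were 5.48 times and r = 0.548, and with a pseudocount of 0.1 r was 0.475. With protein-coding genes only, exons held 2.26%, introns 44.0% and intergenic space 53.7% of the reads. With 5 kb added downstream, genic copies outside exons held 63.0% and intergenic copies 33.5%. More copies then count as genic, but how much of the shift this makes was not computed.

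Percentiles of the gene lists moved with the matching. On 4 length classes they were 91.6 for NF-kB, 96.5 for RNA polymerase III, 58.6 for fibroblast, 71.6 for leukocyte and 0.895 for muscle genes. On length and gene-start distance they were 64.3 for NF-kB, 87.7 for RNA polymerase III, 62.7 for fibroblast, 86.9 for interferon-stimulated, 61.0 for leukocyte and 12.9 for muscle genes. Against random genes they were 82.2 for NF-kB, 91.8 for RNA polymerase III, 61.8 for fibroblast, 71.4 for leukocyte and 19.9 for muscle genes. At 3 reads they were 84.5 for NF-kB, 96.6 for RNA polymerase III, 89.4 for leukocyte and 0.388 for muscle genes, and at 10 reads 85.4 for NF-kB and 0.460 for muscle genes. The libraries lay far apart at 10 reads for the fibroblast list, at 98.9 in replicate 1 and 50.2 in replicate 2. For the leukocyte list they were 69.8 and 97.9. The hepatocyte and housekeeping percentiles differed so much between the libraries that their shifts lay within 1 SD. The hepatocyte list went from 16.2 to 30.1 on 4 length classes and to 8.44 on length and gene-start distance, and the housekeeping list from 76.5 to 59.5 on the latter. The neuronal list stayed at percentile 0 under each of these settings.

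With 2 libraries, leaving 1 out shifts a mean by a fixed part of the SD, so values of each library alone were left out of that count. With each library alone, the share detected ranged from 13.8 to 18.8%, the share of reads in the leading 100 copies from 23.6 to 25.2%, that on chromosome 11 from 13.7 to 14.5%, and the sense minus antisense difference from -2.95 to 1.84 percentage points, changing sign. Assembled chromosomes only and removal of the highest copy moved none of the 14 values recomputed by more than these limits. The contigs left out by the first setting held no reads, so most of its values could not change. The share of signal by B2 subfamily and both alternatives without B3 and B3A were not run, because subfamily names were not used here. No paired analysis was possible because the series holds 1 group.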

Other observations

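The relation of B2 copies to gene starts and to the sequence of exonic copies was looked for after the data were seen. The tests on neighbouring transcripts, on the 3′ stretch and its comparison with a second word, and on differing alignment were also chosen after their results were seen. No biological difference between groups was weighed for the 3 patterns, since the design has 1 group.

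B2 copies close to the start of a protein-coding gene held far more reads than distant ones. Among copies of at least 150 bp, the 3476 within 1 kb of a gene start had a mean of 19.4 CPM in replicate 1 and 14.1 in replicate 2, against 0.808 and 1.01 for the 62039 copies beyond 100 kb, ratios of 24.0 and 14.0. Copies at 1 to 5 kb had 7.55 and 7.76 CPM, those at 5 to 20 kb 4.47 and 4.77, and those at 20 to 100 kb 3.03 and 2.91. The share of copies with at least 1 read did not fall in the same way: it was 22.4% and 27.1% within 1 kb, 24.5% and 31.0% at 1 to 5 kb, 22.8% and 29.7% at 5 to 20 kb, 18.3% and 24.8% at 20 to 100 kb, and 8.79% and 13.7% beyond. Within 1 kb the mean was thus higher than at 1 to 5 kb or 5 to 20 kb, while the share of copies with reads was not. The excess within 1 kb held for copies upstream and downstream of the start and on either strand of the gene, with ratios of 6.93 to 29.3.

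Sequence was read for 6629 exonic copies of at least 150 bp. The stretch TCTGAAGACAGC was picked because it marked detected copies among 3953 of these, so shares by the stretch over all 6629 are not independent of that choice. Among the 2676 copies not used to pick it, 69.5% and 84.3% of the 351 with the stretch had reads, against 9.42% and 12.3% of the 2325 without it. Over all 6629 copies, including those used to pick it, 1403 had a B box but not the stretch. Of these, 29.6% and 36.9% had reads, against 1.97% and 3.29% of 4316 copies with neither. The stretch was present in 27.2% of copies of 185 to 194 bp and in 1.44% of those of 200 bp or more.

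Very high copies carried much of the excess near gene starts, but not all of it. Without the 1000 copies of highest mean CPM the ratio fell from 24.0 to 6.29 in replicate 1 and from 14.0 to 4.50 in replicate 2. Those 1000 copies were chosen by CPM itself. Copy length accounts for little of the excess. With far copies weighted to the lengths of near ones, the ratio of mean CPM went from 24.0 and 14.0 to 21.1 and 12.4. The ratio of shares with at least 10 reads went from 3.53 and 2.55 to 3.11 and 2.25. For upstream copies outside annotated genes and on the opposite strand, where the ratio was 27.6 and 16.0, transcripts from unannotated starts, divergent transcription or read-through of other genes may supply reads, and none of these was separated. For downstream copies on the strand of the gene (17.8 and 20.8, 292 near copies), read-through of the gene's own transcript cannot be told apart from transcription of the B2 copy, because neither strand nor read start was kept in the counts.

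The lack of reads on most B2 copies is not mainly a matter of sequencing depth, since thinning each library to 50% of its reads lost 8.24% and 7.38% of the detected copies, but too few molecules before PCR stay open, as 23621 copies with a median of 6 reads were seen in replicate 2 alone. The gel region stays open: 2.52% and 4.31% of copies under 150 bp and 2.33% and 3.38% of those of 200 bp or more had reads, and the ratio of 1.13 and 1.11 for 130 to 180 bases from copy start to the end of the stretch decides nothing, because it assumes that the stretch is the primer site and uses copies that hold a word picked for detection. TCTGAAGACAGC was picked from 221 words of 12 bases on part of the chromosomes, and on the others copies with it were detected 7.38 and 6.86 times as often, which would fit a primer site. Many words marked detection there. The 128 words starting in the first 90 bases had median ratios of 3.62 and 3.55, and the 93 later words 4.56 and 4.42. The highest ratios in the first 90 bases were 8.14 and 7.54, so a high ratio is not particular to this stretch. The word compared next was picked in the same way from those 128. However, GAGTTCAAATCC, which starts near base 57, well upstream of the stretch, and covers the B box, marked detection as well: it alone gave 62.2% and 76.3%, the stretch alone 66.0% and 86.2%, both 73.6% and 82.2% (ratios of 1.18 and 1.08 for the stretch among copies with this word), and neither 5.62% and 7.70%. A missing primer site, loss of the B box and distance to the B2 consensus or subfamily therefore cannot be told apart: among copies with the stretch, those with a B box were detected 1.19 and 1.02 times as often as those without.

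Sense copies were detected more often than antisense copies in replicate 1 and less often in replicate 2. Copies with few reads are not the source, since at 10 or more reads the difference was 3.09 percentage points in replicate 1 and -1.98 in replicate 2. Trimming or alignment that differed between the libraries may account for the 1.84 and -2.95 points at 1 read, but each kind of input has 1 library, so it cannot be told apart from a difference between the cultures.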
